A study of Xenopus laevis with 8 samples.

How the data were processed

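RNA was profiled from anterior endoderm dissected from Xenopus laevis embryos at Nieuwkoop and Faber (NF) stage 15. Per the labels, every embryo had received mRNA for Ngn3-GR at the 8-cell stage, in 2 dorsal vegetal blastomeres. Ngn3-GR joins the proneural transcription factor Neurogenin 3 to a glucocorticoid receptor domain, and a fusion of this kind is activated by adding dexamethasone. Embryos were then kept with 10 µM dexamethasone (the DEX group, 4 arrays) for 4 hours from stage 12, or without it (the no_DEX group, 4 arrays). The labels call the arrays biological replicates 1 to 4 of each group. No label says whether a replicate number stood for a clutch or a day, and no group with dexamethasone but without Ngn3-GR was analysed here.

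Per the labels' protocols, total RNA was extracted with Trizol, copied into biotin-tagged cRNA from typically 10 µg of RNA, and 15 µg of fragmented cRNA was hybridised to an Affymetrix array. The deposited table held log2 expression values, 1 column per array, and the submitters' processing notes name RMA (background correction, quantile normalization and a summary over the probes of each probe set), with no version given in the sources used here. RMA shrinks differences between weak signals, so changes of dim probe sets are understated. The values ran from 2.02 to 14.5, and the array medians lay between 6.02 and 6.12, so no further scaling was applied. Array background was judged from 17 control probe sets for tags not found in the sample, which ranged from 2.38 to 4.40 with a median of 3.14. Of the probe sets tested, 10319 (31.7%) had a mean at or under 4.40. No pair of arrays held identical values. The number of arrays limits the precision of every value below.

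The table held 32635 probe sets, of which 96 Affymetrix controls were left out and 32539 were tested. Gene symbols came from the platform annotation. It gave 1 symbol for 15495 probe sets and several for 279, which were not named, and it did not list 16765, which stay unnamed. Symbols were updated through the NCBI gene table of assembly Xenopus_laevis_v10.1, which changed 2 symbols and lacked 390 gene identifiers. Xenopus laevis carries most genes as a pair of homeologs, marked .L and .S. Where several probe sets carried a symbol, the one with the highest mean over the 8 arrays stood for the gene, which gave 11303 named genes. For 10 of the 79 genes taken by the naming rule given below the probe set name carries a suffix for probes shared between transcripts.

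Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all probe sets tested), calling a probe set at an adjusted p under 0.05. Every p-value below that is not otherwise named comes from limma. The comparison was fitted without a block, as fixed before the data were examined, and again with the replicate number as a block, an alternative set at the same time because the groups share numbers. Whether the numbers pair the arrays was checked from the deviations of each array from its group mean. Arrays with the same number correlated at 0.63, 0.78, 0.77 and 0.69, against at most 0.20 between different numbers, and all 8 arrays correlated best with their own number. Each correlation exceeded the limit of 0.1, so the numbers were taken to pair the arrays. Adjusted p-values with the replicate block are therefore given beside those without it. In data simulated on the 32539 probe sets, the fit without the block recovered 2 of 67, 45 of 67 and 60 of 66 changes of log2 0.5, 1 and 1.5, with 0 false calls. The fit with the block recovered 51 of 67, 65 of 67 and 66 of 66, with 16 false among 198 calls. The simulated arrays carried the replicate-number effects and the residual spread that the fit with the block had estimated from the real arrays. Better recovery with the block was therefore built in, and is no evidence that the real calls with the block are right.

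Gene lists were compared with all other named genes by limma's camera with a preset correlation of 0.01, adjusted over the 17 lists, and again with a correlation estimated for each list. The lists, fixed before the data were examined, were endocrine transcription factors, neurogenin targets of the neural programme, hormones, secretory granule and exocytosis, Notch pathway, pancreatic progenitor and exocrine, endoderm identity and regions, cell cycle, glucocorticoid-responsive, neural plate and neurons, somitic, cardiac and other mesoderm, notochord and axial mesoderm, epidermis, cement gland and hatching gland, neural crest, blood, endothelium and myeloid cells, migration, adhesion and matrix, and reference genes. Several lists share members, for example insm1, myt1 and neurod4 in the first pair and dll1 in the neurogenin and Notch lists. Members were also counted with p adjusted over the list alone.

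Genes were named by a rule fixed before the data were examined. It took the 15 largest rises and 10 largest falls among genes that passed, or the 5 smallest p in a direction where fewer than 5 passed. From each list it took up to 6 members that passed, or the 2 largest changes where none did. It also took 23 symbols wherever they were measured, of which neurog3, hes6, pax4, arx, pdx1, sst and fkbp5 had no probe set with that symbol. The same rule applied to the fit with the block added 16 genes, after the data had been seen. The values of 2 genes taken by the rule, in the list of migration, adhesion and matrix, are not reported here. Alternatives were quantile normalization, median centring, leaving out the dimmest 30% or 50% of probe sets, a variance trend with robust eBayes, array weights, a random block, other thresholds, the mean over a gene's probe sets, and leaving out each array or pair.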

Results

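The data were 8 Affymetrix arrays of anterior endoderm from Xenopus embryos carrying Ngn3-GR, 4 with dexamethasone and 4 without. Each gave 32539 probe sets on the log2 scale, with array medians of 6.02 to 6.12. Changes are given as log2 of DEX over no_DEX, group levels as mean ± SD over 4 arrays, and pairs are arrays with the same replicate number. The series asked which genes were higher when the fusion was activated.

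With dexamethasone, single genes of several kinds rose or fell. Among the genes that rose were insm1.L, a zinc finger factor of endocrine and neuronal progenitors, myt1.S, a zinc finger factor of the proneural pathway, the Notch ligand dll1.L and cpe.S, which encodes the prohormone-processing carboxypeptidase E. The genes that fell included the retinal homeobox genes vsx1.L and six6.L, the neural gene sox1.S, the signalling gene shh.L and nkx2-1.L, a homeobox gene of foregut and forebrain. These calls were made with the replicate block, where 107 probe sets rose and 73 fell, 180 in all. Without the block, 2 probe sets rose and 0 fell, while 1379 had an unadjusted p under 0.05 against 1627 by chance.

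The 2 genes that rose in both fits were qdpr.L and aif1l.L. Quinoid dihydropteridine reductase, the product of qdpr, regenerates tetrahydrobiopterin, and aif1l encodes an actin-binding protein. The qdpr.L probe set Xl2.16704.1.S1_at measured 7.23 ± 0.25 with dexamethasone and 5.26 ± 0.19 without, a log2 change of 1.97 or 3.93-fold (adjusted p = 0.0107, and 0.00619 with the block). The aif1l.L probe set Xl2.10091.1.S1_at measured 6.41 ± 0.23 and 4.50 ± 0.31, a log2 change of 1.91 or 3.77-fold (adjusted p = 0.0291, and 0.0156 with the block). Both were higher in 4 of 4 pairs.

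With the block, 97 of the 180 probe sets carried a single symbol, and the others stay unnamed. The 97 covered 92 distinct named genes, 52 higher and 40 lower. Over all 180, named or not, the log2 changes were between 0.46 and 2.14 in size. All 180 moved the same way in 4 of 4 pairs, which a call in this paired fit nearly requires and which is no separate evidence. With the block 4070 probe sets had an unadjusted p under 0.05. After qdpr.L and aif1l.L, the largest named rises were hba3.L, an alpha globin, at log2 1.59 (adjusted p = 0.136 without and 0.0171 with the block), from a probe set with shared probes, and zbtb18.S, a zinc finger repressor, at log2 1.41 (0.0714 and 0.0169). A brighter alpha globin, hba-l5.L, looked up after the data were seen, measured 9.76 with dexamethasone and 9.63 without and did not pass (log2 0.13, adjusted p = 0.717 with the block), and neither did hbz.L, at 0.24 within the range of the background controls. Further rises were twsg1.L, a BMP-binding protein, by log2 1.14 and slc3a2.L, the heavy chain of amino acid transporters, from 7.08 ± 0.49 to 8.39 ± 0.57 (2.47-fold, adjusted p = 0.637 and 0.00455). A second slc3a2.L probe set, with a mean of 3.45 within the range of the background controls, did not pass (log2 −0.04, 0.919 with the block). The brighter homeolog slc3a2.S, with a mean of 10.35, did not pass either (log2 0.14, 0.678 with the block). The rise of rfesd.L, log2 1.31, started from a no_DEX mean of 3.27, within the range of the background controls. Smaller rises that also passed with the block were chst10.L at log2 0.84 and dbndd1.L at 1.02, both with an adjusted p of 0.0714 without it.

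The fall of vsx1.L was the steepest among named genes that passed, from 6.99 ± 0.85 to 5.52 ± 0.92, and vsx1.L fell by 1.47 on the log2 scale (adjusted p = 1.00 without and 0.0301 with the block). Next came kctd12.L at −1.19, six6.L at −1.13, the matrix gene tgfbi.L at −1.11 and sox1.S at −1.08. The orphan nuclear receptor genes nr2f1.L and nr2f1.S fell by 0.97 and 0.81 (nr2f1.S to a mean of 3.81, within the range of the background controls), both homeologs of mab21l2, a gene of eye and midbrain development, fell by 0.95 and 0.98, and medag.S fell by 0.96. No fall passed without the block, where the smallest adjusted p among lower named genes was 0.270, for tgfbi.L. The axial gene chrd.1.S, encoding the BMP antagonist Chordin, passed in neither fit (log2 −0.75, adjusted p = 0.423 and 0.0669 with the block).

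The counts of calls changed when arrays were left out. With the block, 34 probe sets were called without pair 1, 4 without pair 2, 26 without pair 3 and 120 without pair 4, each from fewer arrays. Of these calls 30, 4, 19 and 60 were among the 180, and the others were new. With the block and a pair left out, cpe.S passed each time (adjusted p = 0.0120 to 0.0391). By contrast, insm1.L passed only without pair 4 (0.0141), while myt1.S (0.0519 or more) and dll1.L (0.0810 or more) never did. Of the falls named first, vsx1.L passed only without pair 3 and six6.L only without pair 4. The gene sox1.S passed without pair 3 or 4, and shh.L and nkx2-1.L without pair 1 or 4. Without the block, leaving out DEX replicate 2, no_DEX replicate 2 or no_DEX replicate 3 left 0 calls, and leaving out DEX replicate 3 or no_DEX replicate 1 left 1.

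**Figure D1:**
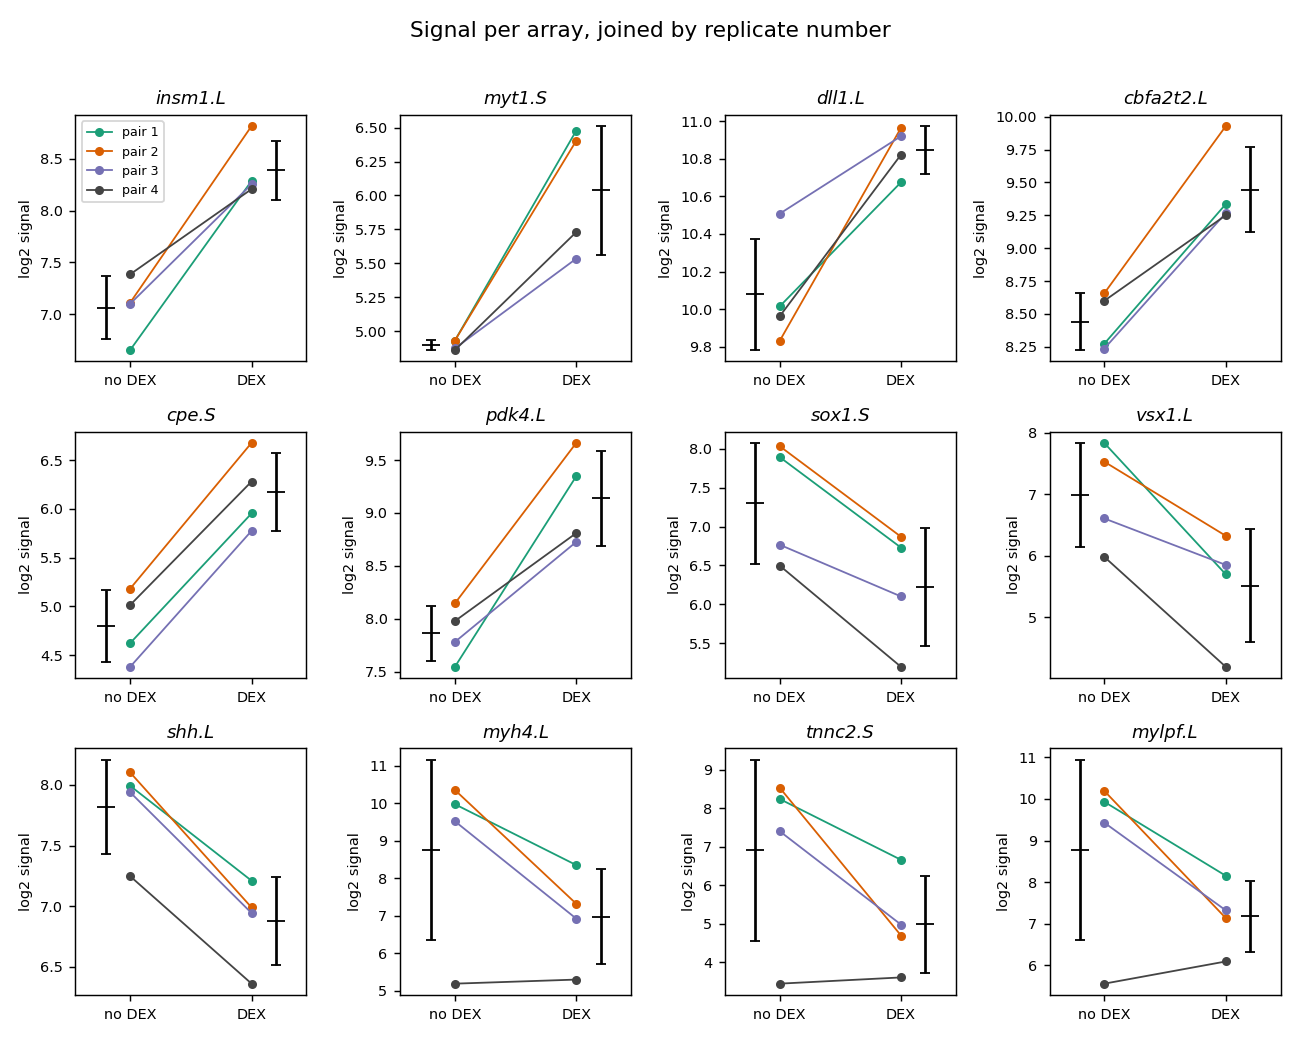
Signal of 12 genes on each of the 8 arrays (vertical axis, log2; the scale differs between panels), without and with dexamethasone. Lines join arrays with the same replicate number, and the black marks beside them are the group mean with 1 SD over 4 arrays. The genes insm1.L to pdk4.L were higher and sox1.S to shh.L lower in 4 of 4 pairs, while the muscle genes myh4.L, tnnc2.S and mylpf.L (the last chosen after its values were seen) were lower in pairs 1 to 3 and higher in pair 4.

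The neurogenin programme had the most calls with the block and the smallest camera p among the lists. Of its 36 measured members, 7 rose, 1 fell and 28 did not pass with the block, and 0 passed without it. When p was adjusted over the list alone, 8 rose and 0 fell without the block, and 15 rose and 3 fell with it. The 7 that rose were insm1.L, myt1.S, dll1.L, the corepressor genes cbfa2t2.L and cbfa2t3.L, the neuronal RNA-binding gene elavl3.L and the growth arrest gene gadd45g.L. The insm1.L probe set went from 7.06 ± 0.30 to 8.39 ± 0.28, a 2.51-fold rise (log2 1.33, adjusted p = 0.139 without and 0.0171 with the block), while a second, dimmer insm1.L probe set, at 5.22 and 5.85, did not pass (log2 0.63, 0.124 with the block). Values for myt1.S went from 4.90 ± 0.04 to 6.04 ± 0.47 (log2 1.14, 0.306 and 0.0287), and cbfa2t2.L rose by log2 1.00, with its other probe set at 0.67 without passing (0.0980 with the block). The rise of cbfa2t3.L, log2 1.12, went from 3.11 to 4.23, both within the range of the background controls. The rise of elavl3.L was log2 0.88, that of dll1.L 0.77 and that of gadd45g.L 0.76. The neuronal tubulin gene tubb3.L fell by 0.63 on the log2 scale. The bHLH gene neurod4.L stood 1.08 higher on the log2 scale in 4 of 4 pairs without passing (adjusted p = 1.00 and 0.168 with the block), and neurod1.S differed by 0.63 and neurod1.L by 0.17, also without passing. As a list the programme shifted up by camera (adjusted p = 3.86e-09, list median log2 0.17; adjusted p = 0.155 with an estimated correlation). Only 8 splits of the arrays into 4 and 4 part all pairs. The real one gave the smallest camera p with the block, but 8 are too few to exclude chance.

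Of the 13 measured endocrine transcription factors, 3 rose with the block and 0 fell, 0 passed without it, and adjusted over the list alone 3 rose and 1 fell without the block (5 and 2 with it). The 3 were insm1.L, myt1.S and runx1t1.L, the last by log2 1.07 (adjusted p = 0.0714 without and 0.0184 with the block). The list did not pass by camera (adjusted p = 0.0555, and 0.224 with the block), but passed with array medians centred (0.0400) and without DEX replicate 3 (0.0323), DEX replicate 4 (0.0402) or no_DEX replicate 2 (0.0434). Neither pax6.L (log2 −0.40, adjusted p = 0.985 and 0.128 with the block) nor nkx2-2.S (−0.11) passed. In the list of secretory granule genes both homeologs of cpe rose with the block, 2 of 27 members. The cpe.S signal went from 4.80 ± 0.37 to 6.17 ± 0.40 (log2 1.37, adjusted p = 0.270 without and 0.00374 with the block), and cpe.L rose by log2 0.54 (0.0424 with the block). Adjusted over the list alone 1 member rose without the block and 2 with it, and the list did not shift (camera adjusted p = 0.314).

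The 10 measured genes of the hormone list were near array background. All 10 had means at or under the highest background control of 4.40, and none passed, with 0 also when adjusted over the list alone (camera adjusted p = 0.590). The insulin homeologs ins.L and ins.S each changed by −0.03 and gcg.L by 0.05, and the largest differences were 0.14 for nts.S and 0.12 for tac1.L. The somatostatin gene sst.1.L, which the list did not hold under that symbol and which was chosen after its values were seen, lay above background at 6.48 ± 0.82 with dexamethasone and fell with the block by 0.72 on the log2 scale (adjusted p = 0.0368, and 1.00 without the block). Its homeolog sst.1.S, at 5.68 with dexamethasone and 5.85 without, did not pass (log2 −0.17, 0.440 with the block). Among 21 pancreatic progenitor and exocrine genes 0 passed in either fit or over the list alone, with ptf1a at 0.05, pnlip.L at −0.28 and nr5a2.S at −0.23 (camera adjusted p = 0.436). No probe set carried the symbol neurog3 or pdx1, so the injected gene could not be checked on these arrays.

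In the Notch pathway, 1 of 24 measured members, dll1.L, rose with the block and 0 passed without it, counted by the probe set that stood for each gene. A second probe set of hey1.S, a Hes-related repressor gene, also rose with the block (log2 0.76, adjusted p = 0.0298), and the one counted did not pass (log2 0.42, 0.220). In counts adjusted over the list alone, 3 rose and 0 fell without the block, and 7 rose and 1 fell with it. The dll1.L signal was 10.85 ± 0.13 with dexamethasone and 10.08 ± 0.30 without (log2 0.77, adjusted p = 0.377 and 0.0419 with the block). The Hes-family repressor genes hes5.2.L and hes5.1.S stood 0.83 and 0.81 higher without passing, while hes1.L (−0.37) and hes1.S (−0.21) were lower in 4 of 4 pairs without passing. Outside this list, hes5.10.L rose by log2 1.16 with the block (adjusted p = 0.0307, and 0.220 without). The list shifted up by camera (adjusted p = 2.68e-05, 21 of 24 members above 0), but did not pass with an estimated correlation (0.155). Its medians in pairs 1 to 4 were 0.21, 0.17, 0.13 and −0.005, so the shift was not seen in pair 4. Splits that part all pairs were too few to exclude chance here too.

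Of 37 genes that respond to glucocorticoids in other systems, 3 rose with the block, 0 fell and 0 passed without it. Without the block 3 rose and 1 fell adjusted over the list alone, and with it 5 rose and 3 fell. Both homeologs of pdk4, a kinase that inhibits pyruvate dehydrogenase, rose, pdk4.L by log2 1.28 (adjusted p = 0.272 without and 0.0244 with the block) and pdk4.S by 1.06 (0.608 and 0.0424). The arrestin-domain gene arrdc2.S rose by log2 0.63 (0.0355 with the block). Its other probe sets, with means of 3.80 and 2.77 within the range of the background controls, stood at 0.23 and −0.01 without passing. The leucine zipper gene tsc22d3.L stood 1.01 higher without passing (adjusted p = 0.0585 with the block), its homeolog tsc22d3.S differed by 0.08, and the kinase genes sgk1.L and sgk1.S by 0.06 and −0.13. The list did not pass (camera adjusted p = 0.0555, and 0.155 with the block).

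Endoderm identity genes went in both directions. Of 43 measured members 2 fell with the block, nkx2-1.L by 0.94 and the liver and myeloid factor gene cebpa.S by 0.66 on the log2 scale, and 0 passed without it. Without the block 2 rose and 0 fell adjusted over the list alone, and with it 9 rose and 10 fell. The nkx2-1.L signal went from 7.02 ± 0.61 to 6.07 ± 0.59 (adjusted p = 1.00 without and 0.0184 with the block). The endoderm determinants sox17a.L (0.29), sox17a.S (0.22), sox17b.1.L (0.26), sox17b.1.S (−0.15) and foxa2.L (0.26) did not pass, and neither did cer1.S, a secreted antagonist of the anterior endoderm, at log2 1.05 (adjusted p = 0.555 and 0.0959 with the block). The list did not shift, and its direction was up without the block (camera adjusted p = 0.474) and down with it (0.827).

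Lists of genes of neighbouring tissues were compared as well. Neural plate genes passed downward as a list (camera adjusted p = 0.00561, list median −0.12), but not with an estimated correlation (0.457). Their medians in pairs 1 to 4 were 0.05, −0.26, −0.16 and −0.22. Of 35 members 1 rose with the block, elavl3.L, 0 fell, and 0 passed without it, and adjusted over the list alone 0 passed without the block, and 2 rose and 7 fell with it. Of the 6 probe sets of pax2.L, all lower in 4 of 4 pairs, 1 that was not the one counted fell with the block (log2 −0.67, adjusted p = 0.0330), and the one counted did not pass (log2 −0.63, 0.112). The midbrain gene en2.S stood at log2 −0.77 without passing. Somitic, cardiac and other mesoderm genes passed downward too (camera adjusted p = 0.0239, list median −0.12), but not with an estimated correlation (0.457). Their medians in pairs 1 to 4 were −0.04, −0.28, −0.25 and −0.01. Of 41 members 1 fell with the block, the cardiac homeobox gene nkx2-5.S by 0.59 on the log2 scale (adjusted p = 0.771 without and 0.0247 with the block). Its other probe sets stood at −0.46 and −0.51 without passing. Adjusted over the list alone 0 passed without the block, and 2 rose and 10 fell with it. Skeletal muscle genes held the widest differences of this list, tnnc2.S with log2 −1.92 and myh4.L with −1.79, and neither passed (adjusted p = 0.170 and 0.134 with the block). Over the muscle fibre genes, a set chosen after the data were seen, the median signal per array was 8.15, 7.03, 6.93 and 6.09 in DEX replicates 1 to 4 and 9.29, 8.54, 8.63 and 5.56 in no_DEX. Over pan-neural genes such as sox2 and sox3, also chosen afterwards, it was 9.69, 9.44, 9.51 and 9.32 in DEX and 9.46, 9.71, 9.75 and 9.73 in no_DEX. The endoderm gene sox17a.L had a mean of 9.98 over the arrays. The pan-neural median was thus far above the highest background control of 4.40 on every array, though only genes with a mean above 4.40 were kept. Signals of different probe sets do not measure relative amounts, and the arrays do not tell which tissue a change came from. The call for neural genes was lost without DEX replicate 4 (adjusted p = 0.0884) or no_DEX replicate 2 (0.114), and the call for mesoderm without DEX replicate 2 (0.150), no_DEX replicate 2 (0.102) or no_DEX replicate 3 (0.319). As small a camera p came from 9 and 8 of the 35 splits of the 8 arrays into 4 and 4, so chance is not excluded for either list.

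Of 18 notochord and axial genes, shh.L fell with the block, from 7.82 ± 0.39 to 6.88 ± 0.36 (log2 −0.94, adjusted p = 0.637 without and 0.0156 with the block), and 0 passed without it. Adjusted over the list alone 2 rose and 2 fell without the block, and 2 rose and 7 fell with it. The matrix gene col2a1.L was at log2 −1.02 without passing. The list passed by camera with the block (adjusted p = 0.0477; adjusted p = 0.691 with the block and an estimated correlation) and not without it (0.0555).

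**Figure D2:**
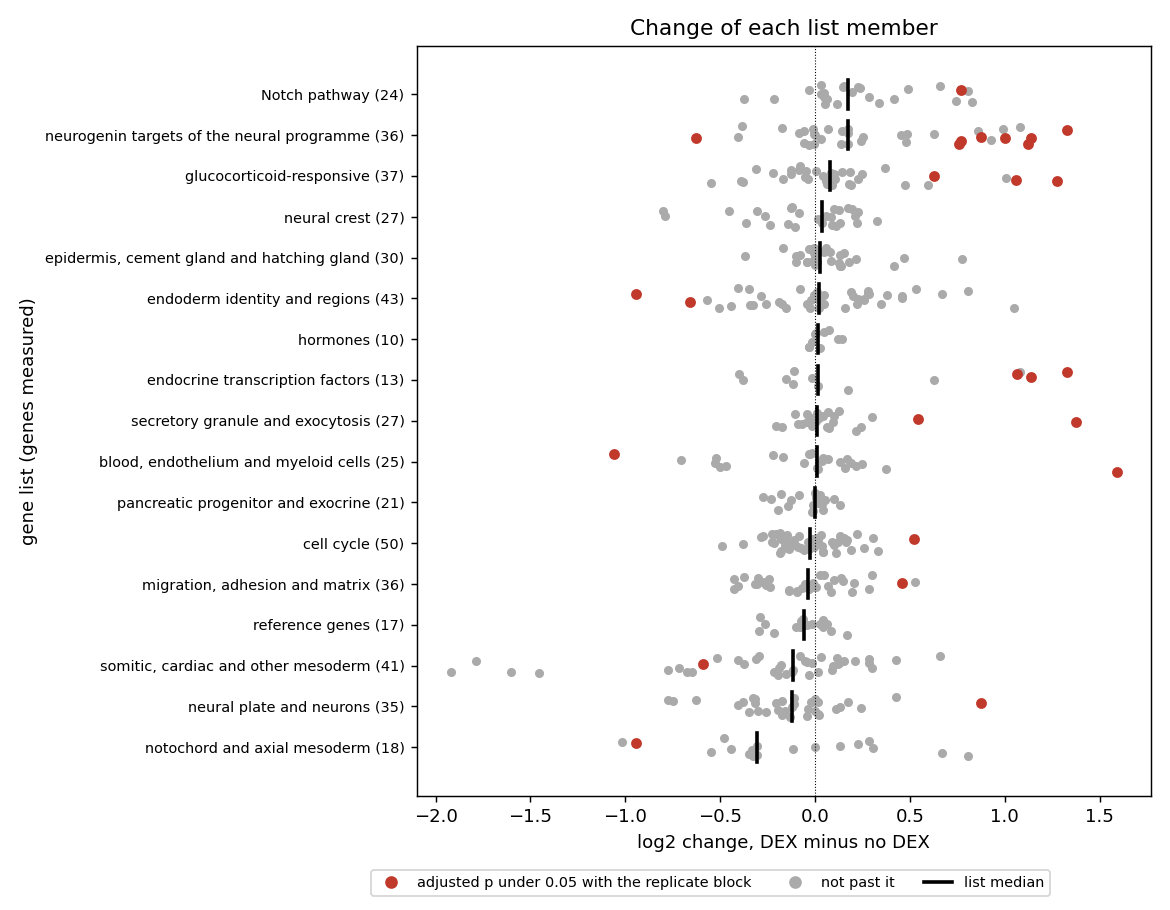
Log2 change of each measured member (points, horizontal axis, DEX minus no DEX) in the 17 gene lists, with the number of genes measured in brackets and a black bar at the list median. Red points had an adjusted p under 0.05 with the replicate block; points are spread vertically at random within a list. The red points of the neurogenin list lie to the right of 0.7 except for tubb3.L at −0.63.

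Blood, endothelium and myeloid genes included 1 rise with the block, hba3.L, and 1 fall, the blood progenitor factor gene tal1.S by 1.06 on the log2 scale (adjusted p = 0.797 without and 0.0169 with the block). A second tal1.S probe set, with a mean of 3.66 within the range of the background controls, did not pass (log2 −0.35, 0.235 with the block). The list held 25 genes, 0 passed without the block, and adjusted over the list alone 2 rose and 1 fell (2 and 5 with the block). Its median was 0.01 and its mean −0.04, and the test pointed down (camera adjusted p = 0.838). In the cell cycle list cdc25b.L, a phosphatase that drives entry into mitosis, rose with the block by log2 0.52 (adjusted p = 0.0381) and did not pass without it, its other probe sets stood at 0.35 and −0.017 without passing, and the other 49 members did not pass. Adjusted over the list alone 0 of the 50 passed without the block, and 1 rose and 1 fell with it, and the cyclin gene ccna1.L was at −0.49 (camera adjusted p = 0.436). Among 36 genes of migration, adhesion and matrix, 1 rose with the block, 0 fell and 0 passed without it. Adjusted over the list alone 1 rose without the block, and 4 rose and 6 fell with it (camera adjusted p = 0.271).

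In the remaining lists 0 genes passed over all probe sets in either fit. The 30 epidermal, cement gland and hatching gland genes included the multiciliated cell genes mcidas.S (log2 0.77, adjusted p = 0.0664 with the block) and ccno.L (0.47), with 0 and 3 rising over the list alone without and with the block (camera adjusted p = 0.0904). The 27 neural crest genes had a median of 0.04 and a mean of −0.06, the test pointed down (camera adjusted p = 0.838), and sox10.L and twist1.L stood at −0.80 and −0.79. Among neural crest genes 0, adjusted over the list alone, passed without the block, and 1 rose and 3 fell with it. The 17 reference genes had a median of −0.06 (camera adjusted p = 0.104), with gapdh.S and hprt1.L both at −0.29, and 0 passed over the list alone in either fit.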

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

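Of the explanations weighed here, the test of dexamethasone alone was set before its result was seen, and the tests on muscle and neural tissue were chosen after.

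Among 158 sets of 4 arrays, 6 held an array far from the other 3, and about 1 in 20, or 7.9, would by chance. The signal of insm1.L in DEX replicate 2 was 8.81, with the nearest of the others at 8.29. In the same array cbfa2t2.L measured 9.93 against 9.34, and twsg1.L measured 9.33 against 9.50. The signal of hes5.10.L in DEX replicate 3 was 8.96 against 9.37. In no_DEX replicate 2, hes1.L measured 11.26 against 10.73. The muscle myosin gene myh4.L measured 5.19 in no_DEX replicate 4, against 9.53 for the nearest of the others.

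Muscle fibre genes were lower with dexamethasone in pairs 1 to 3, with pair medians of −1.58, −2.84 and −1.02, and 0.16 in pair 4, where the signal was already low without dexamethasone. Less somite tissue in the treated dissections could account for this, in which case myod1 and myf5 should be lower by as much. The medians of myod1 and myf5 in pairs 1 to 3 were 0.08, −0.26 and −0.68, above those of the fibre genes in each pair. The myod1 and myf5 median minus that of the fibre genes averaged 1.53 over these pairs (95% interval −1.28 to 4.33), so 3 pairs left this open. Younger treated embryos could also account for it, and the median change of genes active at gastrulation averaged 0.24 (95% interval −0.66 to 1.15), which decided nothing. An effect of activated Ngn3-GR on muscle differentiation stays open as well and was not tested.

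Neural genes that fell with the block averaged −0.93 over the 4 pairs (sox1.S, six6.L, vsx1.L, nr2f1.L, nr2f1.S, nr2e1.S and tubb3.L). If treated dissections had carried less neural plate of every region, pan-neural genes such as sox1, sox2, sox3, zic1 and tubb3 would be lower too. Their median change averaged −0.21 over the 4 pairs (95% interval −0.46 to 0.04), and −0.17 (−0.40 to 0.07) without sox1 and tubb3, which neither shows nor excludes such a loss, and the genes that fell were chosen for falling, so the sizes cannot be set against each other. A smaller share of only the eye or forebrain region may also be involved, as may a response of these genes to Ngn3-GR, and neither was tested.

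The genes that rose may respond to activated Ngn3-GR, to dexamethasone through the embryo's own receptor, or to both. Genes known to respond to glucocorticoids gave a camera adjusted p of 0.0555 as a list, with pdk4.L, pdk4.S and arrdc2.S rising with the block, and 0.0221 to 0.194 when single arrays were left out. Every array came from embryos with Ngn3-GR, so the 2 sources cannot be told apart for any gene named here.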

How the results depend on the processing

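The random block, every change of setting within the fit with the block, and the block with an estimated correlation were chosen after seeing the data, as were the splits by single lists and those of the list count with the block. Signal over background limits dim genes: the dimmest probe sets lie within the range of the background controls, where differences are compressed.

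Without the block the counts of 2 changed, 2 higher and 0 lower probe sets ran from 0 to 3, 0 to 2 and 0 to 1 when single arrays were left out. They were 180, 107 and 73 with the replicate block and 128, 89 and 39 with a random block, which shared 100 calls with the fixed block. The fixed block removes the spread between replicate numbers, and with it the median residual SD went from 0.190 to 0.125. The random block models this spread as a correlation within replicate numbers, estimated at 0.541. At an adjusted p under 0.10 the changed and higher counts were 11 each, and 1 each with the dimmest 50% left out, a filter that removes aif1l.L itself. With the block, leaving out a pair gave 4 to 120 changed, 4 to 47 higher and 0 to 73 lower probe sets, from fewer arrays. Of the 120 changed without pair 4, 60 were among the 180. The block gave 488, 254 and 234 at an adjusted p under 0.10, and 69 higher with the dimmest 50% left out. That filter itself removes dim called probe sets such as that of cpe.S, with a mean of 5.48. Of the 127 calls it left, 119 were among the 180. Other settings with the block gave 127 to 253 changed.

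The 4 list calls became 0 with an estimated correlation and 0 with that and the block, 7 with medians centred, and 3 to 8 with single arrays left out (7 without DEX replicate 3, 8 without no_DEX replicate 4). With an estimated correlation the neurogenin and Notch lists had an adjusted p of 0.155, and the neural and mesoderm lists 0.457; with the block added, all 4 had 0.691. The mesoderm list had 0.0571 with the dimmest 30% left out, cause not tested. Leaving out single arrays gave 0.000167 to 0.114 for the neural list and 0.000200 to 0.319 for the mesoderm list. Centring the medians made the endocrine (0.0400), glucocorticoid (0.0466) and notochord (0.0390) lists pass, and single arrays left out gave the endocrine list 0.0323 to 0.232 and the glucocorticoid list 0.0221 to 0.194, and the notochord list up to 0.611 with 3 of 8 passing. The block made the notochord list pass (0.0477) and changed no other list call.

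The endoderm list turned down with the block (0.827) and with the block and an estimated correlation (0.949), and the blood list turned up with means over probe sets (0.998). Single arrays turned the hormone (0.496 to 0.990), pancreatic (0.188 to 0.847), endoderm (0.0493 to 0.986), cell cycle (0.0434 to 0.880), neural crest (0.242 to 0.865) and blood lists (0.164 to 0.990), of which endoderm passed once upward and cell cycle once downward. Of lists that kept their direction, the epidermal list passed without DEX replicate 3 (0.0323) or no_DEX replicate 2 (0.0163, up to 0.673 elsewhere), the migration list without DEX replicate 1 (0.0311, up to 0.869) and the reference genes without no_DEX replicate 4 (0.0418, up to 0.493). A gene's log2 change is the same under either block, the robust eBayes and the brightness filters, so only the other alternatives could turn a direction. Of the 79 genes taken by the naming rule, 71 kept their direction in each of the 16 alternatives that held them. The dimmest were left out by the filters, which also left no value for the hormone list. The other 8 were small changes that turned when single arrays were left out: tac1.L (−0.018 to 0.26), sox17b.1.S (−0.35 to 0.019), sgk1.L (−0.075 to 0.23), tsc22d3.S (−0.053 to 0.24), nkx2-2.S (−0.30 to 0.082), ptf1a (−0.024 to 0.15), ins.L (−0.11 to 0.069) and ins.S (−0.10 to 0.066).

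Of the 35 splits of the 8 arrays into 4 and 4, 3 gave at least 2 changed probe sets and 3 at least 2 higher ones, shares that do not exclude chance. The other 2 of these part no pairs, however, and of the 8 splits that part all 4 pairs the real one gave 2 and the highest other 0, too few splits for a share under 0.05. For the 0 lower probe sets the comparison has no meaning, as all 35 splits give at least 0. The highest other split gave 2976 (1550 higher), with numbers 1 and 2 on one side and 3 and 4 on the other, which points to a structure by replicate number. With the block, over the 8 splits that part all pairs, again too few, the real split gave 180, 107 and 73 and the highest other 0, so 1 of 8 was as large for each. For the 4 list calls 11 of 35 splits gave as many (median of the other splits 3, highest 9). For the 5 with the block 4 of 8 did (median of the other splits 4, highest 8). A camera p as small came from 1 of 35 splits for the neurogenin list (2.27e-10, lowest other 2.84e-08) and 1 of 35 for Notch (3.16e-06 and 2.33e-05). The arrays are paired, however, and with the block each was smallest in 1 of the 8 splits that part all pairs, too few for a share under 0.05 (1.18e-06, lowest other 1.99e-05, and 3.63e-05, lowest other 8.44e-05). It came from 9 of 35 for the neural list (0.000991 and 7.05e-09) and 8 of 35 for mesoderm (0.00561 and 3.71e-09), and with the block from 2 of 8 and 4 of 8, so chance is not excluded for them.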

Other observations

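The values in this part were looked up after the data were seen, and no explanation of them was tested.

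Several called genes with known roles in development lay outside the rule for named genes. With the block, the craniofacial homeobox gene alx1.L fell by 0.87 on the log2 scale, fst.L, encoding the activin antagonist Follistatin, by 0.85, foxd1.L by 0.62 and the Wnt antagonist gene sfrp2.S by 0.60. The rises included fgf13.L by log2 0.99 (adjusted p = 0.0171 with the block), from a no_DEX mean of 3.75 within the range of the background controls. Another was zbtb18.L, the homeolog of zbtb18.S, by 0.63 (0.0496). The Hes-family gene hes5.3.L stood 1.13 higher in 4 of 4 pairs without passing (0.0585).

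Homeologs of called genes mostly moved alike. Over 2009 homeolog pairs, 62.7% had changes of the same sign. In 29 pairs at least one gene was called, and in 5 of these both were. Both genes had the same sign in 23 of the 29, and in 20 of the 25 without shared-probe suffixes. The median change was 0.76 in the called genes and 0.34 in their partners, counted in the direction of the called gene. Where both were called, the .L gene stood as the called one and the .S gene as its partner. The called genes were chosen for large changes.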
